A study of Mus musculus with 4 samples.

How the data were processed

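RNA was sequenced from the prelimbic cortex, a medial prefrontal area, of C57BL/6 mice aged 8 weeks. There were 4 samples in 4 groups, 1 sample per group. Control and susceptible samples come from an experiment with chronic social defeat, in which mice are repeatedly attacked by an aggressor and those that later avoid social contact are called susceptible. The control sample carries the same stress tag as the susceptible one in the labels, so what the control mice went through is not clear from them. The other pair received adeno-associated virus (AAV) carrying green fluorescent protein (GFP) or CDYL, chromodomain Y-like protein, a chromatin corepressor. Whether a sample was 1 mouse or a pool is not stated. Per the labels' protocols, RNA was extracted with Trizol from frozen tissue, and libraries were made from 1 µg of total RNA with a NEBNext Ultra kit, which does not mark strand.

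The authors deposited 1 table per pair. Each gives FPKM (fragments per kilobase of transcript, scaled to library size) for both libraries, with gene positions. Per the submitters' processing notes the values come from Cuffdiff on the mouse build mm10; the aligner, annotation and versions are not given in the sources used here. There are 12318 genes in the stress table and 15396 genes in the AAV table. In both, no gene with values above 0 in both libraries differed by less than 0.32 on the log2 scale, so genes closer than that carry no value here, and an absent gene is not thereby shown to be alike. List medians are therefore medians over listed genes. The p-values and q-values deposited by the authors belong to a comparison of 1 column with another, and are printed only as theirs. The column for the susceptible sample was matched to its title although the name in the header lacks a letter; 0 per-sample columns were left unmapped. The tables were normalized separately, so differences were taken within a table unless stated otherwise.

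Depth was read from the steps between low FPKM values of genes with 1 annotated transcript of 3 to 20 kb (GENCODE M21, the same build). In each library at least 92.9% of values under 4.5 steps lay within 0.15 of a whole step. The step gave an effective depth of 14300000 fragments for control, 23200000 for susceptible, 22600000 for AAV-GFP and 24000000 for AAV-CDYL, which includes the authors' scaling and ignores fragment length. At FPKM 1, a transcript of 2 kb was then backed by about 28.7, 46.3, 45.3 and 48.0 fragments. Values of 0 are reported as listed at 0, without a fold. About 31.2% of the genes in the stress table and 33.3% in the AAV table shared a Cuffdiff locus with another listed gene, and fragments of such genes, of close paralogs (immunoglobulin segments, H2 genes, ribosomal protein genes with their pseudogenes, chemokines) and of overlapping or antisense genes cannot be assigned with certainty.

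With 1 library per group, no difference here has a replicate check, and no p-value was computed. The following choices were made before the data were examined. A gene counted as higher or lower where log2(FPKM + 1) differed by at least 1.5-fold, among genes at FPKM of at least 1 in either library; this scale understates differences of low genes, and folds quoted for single genes are ratios of the FPKM values. For each of 38 gene lists with at least 5 such genes, the median difference was set among 10000 random lists of the same size matched on mean expression in 20 bins; lists below the 2.5th or above the 97.5th percentile are said to stand apart, which describes these libraries only. The comparisons were related by Pearson and Spearman correlations across genes and by overlaps beside the overlap of independent lists. The authors' calls were counted at q under 0.05. The rule for named genes took the study's own genes (Cdyl, Vgf, Bdnf, Scn8a, Rhoa); the 8 largest differences per direction at a mean FPKM of at least 2, among the authors' calls where 8 or more existed, without unnamed genes; and up to 3 members per list with the largest difference. Not every gene that the rule took is named in the results.

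The procedure was tested on simulated data. For the stress pair, 97 of 100 raised and 92 of 100 lowered genes, all by 2-fold, were recovered, and 4 of 100 lists of unchanged genes stood apart, while for the AAV pair these were 96, 98 and 7. Changed genes were drawn only at a mean FPKM of at least 5, and noise was independent for each gene. The simulation did not leave out genes with small differences or apply the floor to simulated values. These rates are therefore not error rates for the deposited tables. Alternatives tried were pseudocounts of 0.1 and 0.5, no floor and a floor of 5 FPKM, a 2-fold rule, centring on the median, scaling to a common upper quartile, and other thresholds on the authors' values; further ones were chosen after seeing the data and are given as such. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions are those of the deposited tables, in mm10.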

Results

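Gene expression was measured by RNA sequencing in the prelimbic cortex of mice in 2 comparisons, each of 1 library with 1 library: stress-susceptible against control mice, and mice given AAV-CDYL against mice given AAV-GFP. The first asks which genes differ between susceptible and control, the second which genes differ when CDYL is overexpressed in the same area. Differences of the first pair are called after stress, although the labels leave unclear what the control mice went through. All values are FPKM from the authors' tables, with no replicates, so differences describe these libraries. Effective depth was 14300000 fragments for control, 23200000 for susceptible, 22600000 for AAV-GFP and 24000000 for AAV-CDYL.

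In the susceptible library, myelin and glucocorticoid-responsive genes were higher than in the control library, immediate early genes were lower, and several inflammatory genes that were low in control were higher. In the oligodendrocyte and myelin list all 18 listed members were above control, 16 of them by at least 1.5-fold, with a median difference of 1.15 on the log2(FPKM + 1) scale, above all 10000 random lists. Mobp, a structural protein of compact myelin (chromosome 9, 120149742 to 120181484), stood at 60.9 FPKM in control and 303 in susceptible, a 4.98-fold difference. Mal, a myelin proteolipid, stood at 23.4 and 89.5, and Cldn11, the claudin of myelin tight junctions, at 16.6 and 57.5. Apod, a lipid carrier made by glia (chromosome 16, 31296192 to 31314808), had the largest difference on that scale among the named authors' calls, 17.4 against 237 FPKM, or 13.6-fold. Hapln2, a link protein of the matrix at nodes of Ranvier, stood at 1.99 and 13.8.

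Inflammatory genes were mostly low in control, and a gene under 1 FPKM there enters a count only if its susceptible value is higher. Of 19 expressed cytokines and inflammatory mediators, 13 were higher and 1 lower (median 1.19, above all random lists). Among the 9 at 1 FPKM or more in control, a restriction chosen after seeing the data, 3 were higher and 1 lower, and the list no longer stood apart (median 0.40, percentile 86.3), as with a floor of 5 FPKM. Lcn2, an iron-binding acute-phase protein, stood at 8.27 and 44.4, Serpina3n, a protease inhibitor of reactive astrocytes, at 5.27 and 28.3, and complement gene C4b at 0.530 and 6.66. The neutrophil chemokine Cxcl2 was listed at 0 in control and at 4.54 in susceptible. Interferon-stimulated genes (9 of 13 higher, median 0.88, percentile 99.97) and antigen presentation genes (9 of 14, median 0.78, percentile 99.91) had low levels. Only 4 and 8 of them reached 1 FPKM in control, of which 2 and 3 were higher; the antigen presentation list still stood apart over those 8 (median 0.55, percentile 99.2), but not with a floor of 5 FPKM (median 0.48). Isg15 stood at 0.268 and 3.03, and Cd74 at 0.952 and 5.12. In the erythrocyte and leukocyte list 5 of 10 genes were higher and 2 lower, with a median of 0.74 (percentile 99.97) that became -0.34 with a floor of 5 FPKM and 0.076 (percentile 84.9) over the 8 genes at 1 FPKM or more in control. The neutrophil granule genes Ngp (3.27 and 20.9) and S100a8 (38.02 and 150) were among those higher, as was Ltf, lactoferrin, outside that list (1.30 and 13.2). The erythroid gene Alas2 differed by 0.49. Blood left in the tissue was not tested as a cause in this pair. Microglia and macrophage markers did not stand apart (2 of 12 higher, 4 lower, median -0.35). P2ry12, in a locus shared by 6 listed genes, was lower (25.4 and 7.85), as was Trem2 (18.4 and 6.28), while Cd68 was higher (3.46 and 7.84).

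Of 15 glucocorticoid-responsive genes, 9 were higher and 1 lower in the susceptible library, with a median of 0.79, above all random lists. Sult1a1, a sulfotransferase, stood at 3.87 and 17.5, the arrestin-domain gene Arrdc2 at 1.64 and 7.55, and Hif3a at 0.580 and 4.11. Immediate early genes, which neurons switch on with activity, formed the only list below the random lists: 13 of 23 were lower and 0 higher, with a median of -0.82. The transcription factor Egr2 stood at 6.15 in control and 0.787 in susceptible, the synaptic regulator Arc at 76.2 and 21.2, and Fos at 26.1 and 8.86. Homer1, a postsynaptic scaffold that belongs to the same list, stood at 101 and 45.1.

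Endothelial, astrocyte and striatal neuron markers also stood above random lists, while pericyte, smooth muscle and meningeal markers (5 of 11 higher, median 0.50, percentile 90.4) and olfactory markers (2 of 6 higher, median 0.36, percentile 63.9) did not. Endothelial markers were higher for 9 of 14 genes (median 0.65, percentile 99.94), led by Vwf, von Willebrand factor (3.98 and 45.3), and Ly6c1 (40.0 and 124). Of 17 astrocyte markers only 7 were listed, 3 of them higher by the size rule (median 0.56, percentile 99.21). Of the 7, 6 lay above control, while the water channel gene Aqp4 lay below (-0.56). Gfap, the astrocyte filament protein, stood at 2.92 and 31.0, in a locus shared by 4 listed genes. Striatal neuron markers were higher for 8 of 11 (median 0.88, percentile 99.96; 4 of the 7 at 1 FPKM or more in control, median 0.73, percentile 99.6), including Penk, proenkephalin (5.93 and 15.9), and the dopamine receptor gene Drd2 (0.558 and 2.44). Ptgds, prostaglandin D synthase, a member of the pericyte, smooth muscle and meningeal list, stood at 125 and 592. Choroid plexus and ependymal markers had too few expressed members for a percentile: 3 of 3 were higher, 1 of them at 1 FPKM or more in control, and with CDYL 4 of 4 were higher, 1 of them at 1 FPKM or more with AAV-GFP. Levels were also higher in the susceptible library for the dopamine-synthesis enzyme gene Ddc, at 1.83 and 13.3. Ribosomal protein genes, of which 14 of 49 were listed, stood slightly apart (13 above control, 3 by the size rule, median 0.39, percentile 97.94). This call was not kept with a floor of 5 FPKM. Nor was it kept among genes at 1 FPKM or more in control, where the 14 members kept their median at percentile 96.965. Synaptic and channel lists did not stand apart: the medians were -0.40 for 14 listed sodium and potassium channels of 29, -0.43 for 6 synaptic vesicle genes of 26 and -0.41 for 7 postsynaptic density genes of 24.

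Among the study's own genes, Cdyl (ENSMUSG00000059288, chromosome 13, 35659862 to 35874064) stood at 1.98 FPKM in control and 2.54 in susceptible, a difference of 0.25 that the size rule did not count. Vgf, a secreted neuropeptide precursor (ENSMUSG00000037428, chromosome 5, 137026392 to 137033351), stood at 177 and 127, and Bdnf, a neurotrophin, at 10.8 and 7.94; neither passed the size rule. In the authors' deposited table each of these genes has q = 0.999. Vgf was singled out by the study from these samples, so its value is not independent evidence.

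By the size rule 1006 genes were higher and 575 lower in the susceptible library, of 5334 at FPKM of at least 1. The authors' deposited table has 35 genes higher and 6 lower at q under 0.05. The lower ones include Arc and the 18S ribosomal RNA related sequence Rn18s-rs5 (506 and 129 FPKM). Apart from Rn18s-rs5, none of the 8 largest negative differences among named genes had such a call: Klf8 stood at 14.9 and 1.09, the transcription termination factor gene Ttf1 at 15.6 and 2.38, and Pde6h at 76.8 and 0.0195, the last in a locus shared with another listed gene. Centring on the median of listed genes (0.24) turned the split to 532 higher and 1918 lower, while a centre estimated from a normal fit to the listed genes (-0.04), chosen after seeing the data, gave 1147 and 481.

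In the AAV-CDYL library, Cdyl stood at 1052 FPKM against 2.68 in the AAV-GFP library, a 393-fold difference in the direction of the label. Immunoglobulin genes made up the other 7 of the 8 largest positive differences: Igkc, the kappa constant region (chromosome 6, 70726435 to 70726966), was listed at 0 with AAV-GFP and at 1407 with AAV-CDYL, Ighg2b at 0 and 166, and the variable segment Ighv2-9 at 0 and 311. Of 140 expressed immunoglobulin and T-cell receptor segments, 136 were higher and 3 lower. Of the 8 at 1 FPKM or more with AAV-GFP, 4 were higher and 3 lower. The floor fixes the direction of the other segments, which entered through their AAV-CDYL values, but not the size of their differences. Reads can be shared among such segments. Antigen presentation genes were higher for all 17 expressed members, with a median of 4.77, and interferon-stimulated genes for all 25, with a median of 3.98; both lay above all 10000 random lists. The 13 interferon-stimulated and 9 antigen presentation genes at 1 FPKM or more with AAV-GFP were all higher too, with medians of 3.91 and 4.77. Cd74, the invariant chain of class II molecules, stood at 1.26 and 335, the class II gene H2-Aa at 0.191 and 134, the interferon-induced genes Oasl2 at 0.834 and 83.6 and Ifitm3 at 3.95 and 206. Of 28 cytokines and inflammatory mediators, 25 were higher and 0 lower (median 1.70, above all random lists), and 8 of the 11 at 1 FPKM or more with AAV-GFP were higher (median 1.16, percentile 99.99); the T-cell chemokine Ccl5 was listed at 0 and 151, Ccl12 at 0 and 37.0, and C4b stood at 0.545 and 80.0.

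Leukocyte and glial markers were higher alongside. In the erythrocyte and leukocyte list 10 of 11 genes were higher and 1 lower (median 1.75, percentile 99.99). These 10 were under 1 FPKM with AAV-GFP and entered through their AAV-CDYL values, so the floor fixes their direction. It does not fix the size of their differences. Random lists of matched expression had a median of 0.47, but were not matched on the share of such genes. The T-cell receptor subunit Cd3g was listed at 0 and 7.30, the cytotoxic-cell gene Nkg7 at 0 and 5.34, and Ptprc, the pan-leukocyte CD45, stood at 0.553 and 11.6. Microglia and macrophage markers were higher for 15 of 16 (median 2.46, above all random lists), with the complement genes C1qa at 32.6 and 404 and C1qb at 27.7 and 310, and the lysosomal protease Ctss at 29.96 and 401. Oligodendrocyte and myelin markers were higher for all 19 (median 1.77, above all random lists). Mobp stood at 60.6 and 285, and Cldn11 at 18.3 and 86.5. The iron carrier Trf stood at 25.8 and 177, with 63.5% of its exonic bases also in Gm20425. Astrocyte markers were higher for 9 of 13 and lower for 1 (median 0.69, percentile 99.82): the water channel Aqp4 stood at 10.1 and 43.8 and Gfap at 5.85 and 386, in a locus shared by 7 listed genes, while Gjb6, a connexin, was lower (44.7 and 19.5). All 47 listed ribosomal protein genes were above AAV-GFP, 26 by the size rule (median 0.61, percentile 99.98), such as Rps29 at 233 and 498.

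Ion channel, receptor and synaptic lists were lower in the AAV-CDYL library. Voltage-gated sodium and potassium channels were lower for 21 of 25 (median -0.78), glutamate receptors for 10 of 17 (median -0.65), both below all random lists. Kcnq3 stood at 23.3 and 11.2, Scn4b at 9.19 and 4.09, and the NMDA receptor subunit gene Grin2a at 24.2 and 9.27. Postsynaptic density genes were lower for 14 of 23 and higher for 1 (median -0.73, below all random lists), with Homer1 at 109 and 37.2 and Shank1 at 127 and 62.2. Synaptic vesicle genes were lower for 13 of 25 (median -0.59, percentile 0.05), with the calcium sensor Syt1 at 591 and 327. GABA genes (6 of 15 lower, median -0.58, percentile 1.18), monoamine receptors (6 of 17 lower and 1 higher, median -0.47, percentile 0.05) and neurotrophin signalling (4 of 8 lower and 1 higher, median -0.61, percentile 0.65) also stood below. Examples were Gabrb2 at 68.1 and 37.2, the adrenergic receptor gene Adra1d at 30.4 and 10.6, and Shc3 at 30.9 and 14.5. Immediate early genes were lower for 11 of 20 and higher for 1 (median -0.60, percentile 0.01), led by Egr3 at 66.7 and 19.3, and circadian clock genes were lower for 8 of 14 and higher for 2 (median -0.60, percentile 0.19), with Per2 at 9.38 and 4.46. Excitatory neuron markers did not stand apart (3 of 8 lower, median -0.54, percentile 9.11), although all 8 were below AAV-GFP, such as Camk2a at 665 and 395. Interneuron, upper layer, deep layer and striatal neuron markers and neuropeptides did not stand apart either. Whether the lower channel, receptor and synaptic lists reflect a lower share of neuronal RNA was not tested.

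Of the study's genes, Vgf stood at 184 FPKM with AAV-GFP and 124 with AAV-CDYL, Bdnf at 12.5 and 8.57, the sodium channel gene Scn8a (chromosome 15, 100869858 to 101045938) at 47.9 and 27.0, and the small GTPase gene Rhoa at 68.4 and 91.4. Of these 4, only Scn8a passed the size rule, and in the authors' deposited table each has q = 0.999, while Cdyl has q = 0.00727. Cdyl2, a paralog of Cdyl, stood at 8.99 and 4.48, and the histone deacetylase gene Hdac1 at 11.8 and 16.8; the CDYL-associated repressor list did not stand apart (median 0.44, percentile 60.03).

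**Figure D1:**
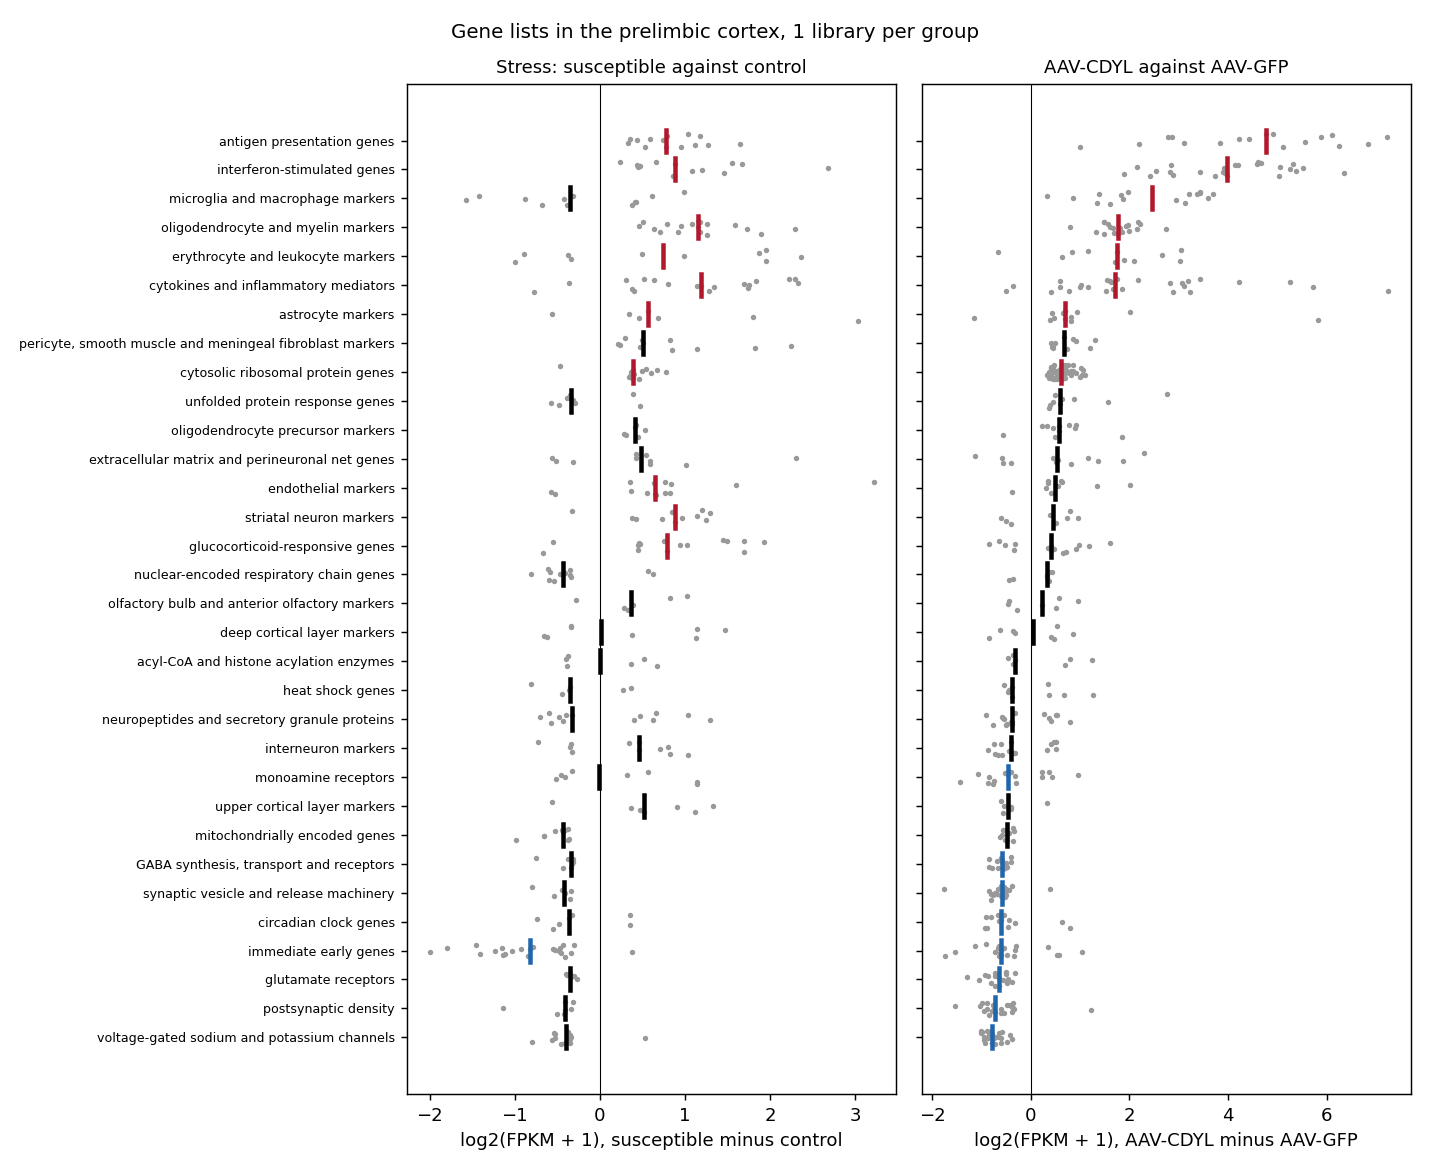
Differences in log2(FPKM + 1) for members of each gene list, susceptible minus control on the left and AAV-CDYL minus AAV-GFP on the right, on separate horizontal scales. Each grey point is a gene and each bar a list's median over listed genes, red where above and blue where below the matched random lists; the myelin median is 1.15 on the left and 1.77 on the right, and the gap around 0 reflects the smallest difference the tables list.

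By the size rule 2516 genes were higher and 1159 lower in the AAV-CDYL library, of 8047. The authors' deposited table has 147 genes higher and 0 lower at q under 0.05, and 794 higher and 49 lower at an unadjusted p under 0.05; 45 of the 147 are immunoglobulin or T-cell receptor segments. Centring on the median of listed genes (0.30) gave 1630 higher and 3572 lower, and the centre from a normal fit (-0.10), chosen after seeing the data, 2916 and 705. No list described as standing apart in either comparison changed sign under median centring or upper-quartile scaling. Rn18s-rs5 stood at 691 and 137, lower in the AAV-CDYL library as in the susceptible one. Other genes cover 73.9% of its exonic bases.

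The pairs share no library, and their differences were set side by side to ask whether genes that differ after stress also differ with CDYL. Across the 3242 genes passing the floor in both tables, Pearson's r was 0.511 and Spearman's rho 0.606, and 82.3% of genes had the same sign; genes are not independent replicates, and genes with smaller differences than the tables list are absent from this set. There were 491 genes higher in both, where independent lists of these sizes would share 248, and 140 lower in both, against 58.6. Opposite directions were rarer than for independent lists: 31 genes were higher after stress and lower with CDYL (against 125), and 37 the reverse (against 116). A gene under 1 FPKM in both control and AAV-GFP enters this set only if it is higher in both treated libraries. The floor thus favours equal signs, and the counts for independent lists are not those of unrelated changes. How much of the overlaps and correlations this accounts for was not tested. Myelin markers were higher in both for 16 of 18 genes, and interferon-stimulated and antigen presentation genes for 9 of 13 and 9 of 14. Of the latter 2 lists, only 2 and 3 of the genes higher after stress reached 1 FPKM in control. The floor fixed the direction of the others after stress. Immediate early genes were lower in both for 9 of 16. Some lists of cell composition and housekeeping had the same sign in both comparisons for all shared members: ribosomal protein genes for 12 of 12, mitochondrially encoded genes for 8 of 8, endothelial and pericyte markers each for 8 of 8 and striatal neuron markers for 6 of 6. Others did not: microglia and macrophage markers had the same sign for 5 of 12, astrocyte markers for 4 of 6, upper layer markers for 1 of 3, and excitatory neuron markers and nuclear respiratory chain genes each for 1 of 2. Across the authors' deposited tables, there were 12 genes called higher in both comparisons, against 0.322 for independent lists, among them Apod, C4b, Cldn11, Mobp and Serpina3n. Also among the 12 were Ccl4, Hcar2, Igkc, Irg1, Serpina3g and Tgm1, each listed at 0 in control and in AAV-GFP. Such genes can only be called higher, so 0.322 is not the overlap of unrelated calls.

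**Figure D2:**
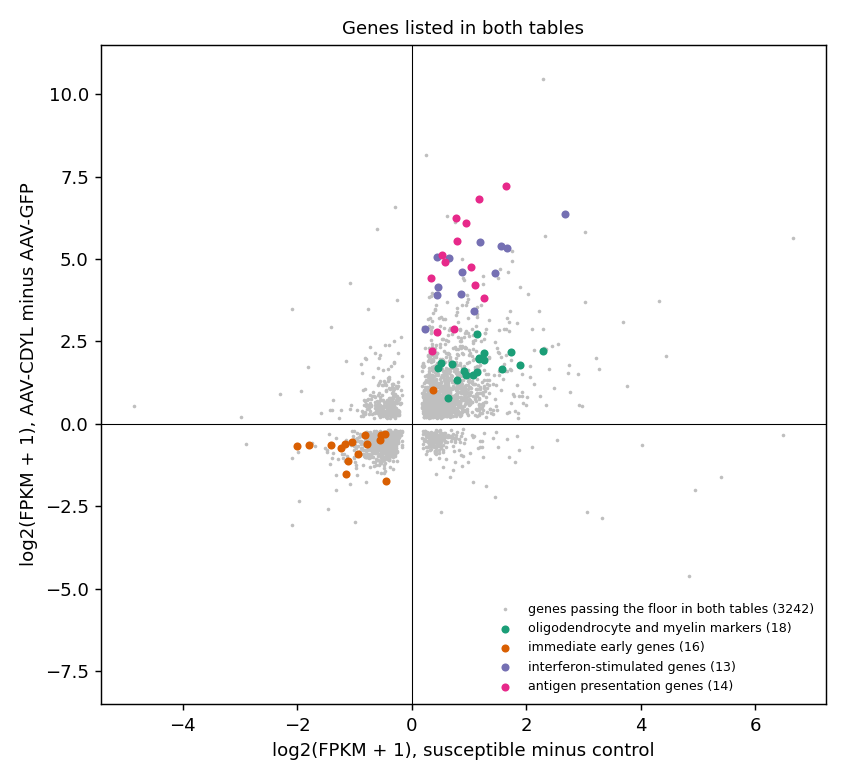
Difference in log2(FPKM + 1) for each of 3242 genes, susceptible minus control on the horizontal axis and AAV-CDYL minus AAV-GFP on the vertical axis. Coloured points are members of 4 lists; the 18 myelin markers lie at the upper right, as do the 13 interferon-stimulated and 14 antigen presentation genes, and 15 of 16 immediate early genes at the lower left.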

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

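The normal-fit centre, the gene subsets and the restriction to genes at 1 FPKM or more in the control or AAV-GFP library were chosen after seeing the data; the other alternatives were planned. Of 98 alternative values of the main results, 77 stayed close to the main one (counts within 1.5 times), those of Cdyl and the correlations among them (Pearson's r 0.503 to 0.558, Spearman's rho 0.583 to 0.624). With a floor of 5 FPKM, 483 genes were higher after stress and 1416 with CDYL, 233 were higher in both, and 6 rather than 10 lists stood above random lists after stress; fewer genes enter by construction. Under the 2-fold rule 366 were higher and 136 lower after stress, 1424 and 145 with CDYL. Centring on the median of listed genes gave 532 higher and 1918 lower after stress, 1630 and 3572 with CDYL. That centre is doubtful, since the tables omit genes near it: at a mean FPKM of at least 5, listed genes under 1.5-fold lower outnumbered those under 1.5-fold higher (1241 against 727 after stress, 1839 against 809 with CDYL). The normal-fit centre gave 705 lower with CDYL. A pseudocount of 0.1 gave 742 genes higher in both comparisons and 214 lower in both, by construction, as low genes then differ more. Of the authors' calls after stress, q of 0.01 left 0 higher and 0 lower, since their smallest q is 0.0225; an unadjusted p of 0.05 gave 384 and 150, and 794 and 49 with CDYL. The erythrocyte and leukocyte median after stress turned to -0.34 with a floor of 5 FPKM; the cause was not tested. Of the alternative list medians, 313 kept their side of the percentile limits, 7 gained and 6 lost a call without turning sign, and of the named-gene settings 436 kept their side of the size rule, 9 gained and 5 lost it. Median centring moves list members and random lists by the same amount, so under it every list kept its side of the percentile limits by construction. The planned replicate alternatives were not run, and lists with under 5 genes at the higher floor or under that restriction gave no value. No paired analysis was possible because each group held 1 library. Depth limits low genes most in the control library.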

Other observations

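Mitochondrially encoded genes were below the reference library for all 10 listed members after stress (median -0.44, percentile 13.3) and all 12 with CDYL (median -0.49, percentile 5.82), without standing apart; mt-Atp8, in a locus shared by 3 listed genes, stood at 18201 and 9207 FPKM after stress. Upper cortical layer markers lay above control for 6 of 7 genes after stress (median 0.52, percentile 96.3; over the 6 at 1 FPKM or more in control median 0.49, percentile 98.45, above the limit, as with a pseudocount of 0.1, median 0.81), with Otof at 0.754 and 3.42, and below AAV-GFP for 5 of 6 with CDYL (median -0.47, percentile 14.5). Interneuron markers had medians of 0.46 (percentile 96.5, and 97.6 under that restriction, also above the limit) and -0.41 (percentile 4.37), with the interneuron peptide gene Vip at 12.7 and 27.2 after stress and Pvalb at 21.7 and 12.6 with CDYL. Unfolded protein response genes were above AAV-GFP for all 9 listed members (5 by the size rule, median 0.60, percentile 96.5), led by Atf3 at 0.508 and 9.29. Lists of acyl-CoA and histone acylation enzymes (percentiles 68.6 and 55.4), neuropeptides (48.1 and 12.4), deep layer markers (47.05 and 63.2), oligodendrocyte precursors (84.3 and 87.97), pericytes and meningeal cells (90.4 and 86.5), olfactory markers (63.9 and 23.1), heat shock genes (36.5 and 31.02) and nuclear respiratory chain genes (11.1 and 70.2) did not stand apart in either comparison, given after stress and then with CDYL. The pericyte and meningeal list did stand above random lists with CDYL over its 8 genes at 1 FPKM or more with AAV-GFP (5 higher, median 0.80, percentile 99.1), and after stress with a pseudocount of 0.1 (median 1.01). With CDYL, glucocorticoid-responsive genes (6 of 15 higher and 2 lower, median 0.41, percentile 90.8) and endothelial markers (4 of 10 higher, median 0.49, percentile 85.9) did not stand apart. The metallothionein gene Mt2 stood at 104 and 318, but 73.5% of its exonic bases also lie in Gm45774. Extracellular matrix genes did not stand apart (median 0.48 after stress, 0.53 with CDYL), except with a floor of 5 FPKM (0.59 and 0.83), yet the node link-protein gene Hapln2 was higher in both, at 1.28 and 10.2 with CDYL.

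All tests below were chosen after the results were seen, and the biological explanations, stress and CDYL, were not separable from the library in either pair. The first pattern is that myelin genes were higher in both treated libraries. For the AAV pair, a difference in depth is argued against as the cause, since the median was 1.77 there and effective depths differ by 1.06-fold. Those of the stress pair differ by 1.62-fold, and depth was not tested as a cause in that pair. A dissection that reached white matter and striatum may account for the stress pair, where striatal neuron markers stood above the random lists. Their median was 0.88, and 0.73 over the 7 of 11 at 1 FPKM or more in control. Other lists hold 4 of the striatal list. Upper cortical layer markers were above control too (6 of 7, median 0.52, percentile 96.3), so the striatal markers alone do not decide it. Choroid plexus and ependymal markers were higher for 3 of 3 in the stress pair and 4 of 4 in the AAV pair. Most came from under 1 FPKM, where the floor admits only genes that are higher. In the AAV pair the striatal median of 0.44 (percentile 78.2), which turned to -0.41 with a floor of 5 FPKM, leaves this open, because white matter can be included without striatum.

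The second pattern is the high level of immune genes in the AAV-CDYL library. Scaling of the libraries does not account for it, since the lowest median of the interferon-stimulated genes under any alternative was 3.68. Blood left in the tissue stays open for the leukocyte genes: the erythroid gene Alas2, singled out after its value was seen, differed by -0.67, but it lies near the floor and haemoglobin genes have no value in that table. A response to the injection or to the vector in that sample, rather than to CDYL, cannot be told apart from an effect of CDYL with 1 library per group. The interferon-stimulated genes had a median difference of 0.072 between the AAV-GFP and control libraries over 17 genes listed in both tables, which were normalized separately. Of the 13 that passed the floor in the stress pair, only 4 reached 1 FPKM in control, and the scale understates differences of low genes. This value therefore leaves a response to the vector open.

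The third pattern is that Vgf had lower values in both treated libraries, although neither difference passed the size rule, and no test decided on an explanation. A lower share of neuronal RNA may contribute with CDYL, where Vgf differed from the median of the 8 listed excitatory neuron markers by -0.028. That match is largely set by the table, which lists no gene near 0: random lists of matched expression had a median of -0.41, and these markers did not stand apart (percentile 9.11). After stress only 4 of the markers were listed, and the difference of -0.37 leaves a lower share open too. Lower neuronal activity also stays open: the immediate early genes had a median of -0.82 after stress and -0.60 with CDYL, but too few neuron markers were listed after stress to set beside them, and with CDYL the neuron markers lay at -0.54.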
